A study of Mus musculus with 12 samples.

How the data were processed

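RNA from epididymal fat of male mice was measured on an Illumina mouse bead array. The 12 samples were pools of RNA, 3 pools for each of 4 groups: wild type and Siah2 knockout mice on a diet with 10% or 45% fat. The wild type groups and the low fat knockout group held 10 animals each, combined as 3 or 4 animals per pool, and the high fat knockout group held 8 animals in pools of 2 or 3. Which pool held how many animals is not given in the sources used here. A pool averages its animals, so the spread between pools is not the spread between single animals.

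The deposited values used for every comparison were normalized intensities, 1 per probe and sample, made by the authors with GenomeStudio. Its version and settings are not stated. The values were linear, with 22.9% of them below 0 and a lowest value of -27.5, which shows that a background had been subtracted. The medians of the 12 columns lay between 33.3 and 33.6, and all sorted columns held equal values, within 1e-09, at 38.2% of the ranks, so the authors had also brought the arrays to a common distribution. Further deposited tables held raw bead signals, an arbitrary intensity unit (other than a count) without normalization, and the detection p-value of each probe on each array. Their columns carried array codes that no label tied to a sample. They were used for gene names, for the number of arrays that detected each probe and for the range of raw brightness, and 20 signal columns of a gene-name table of 32 arrays belonged to no sample of the series. The tables were joined row by row on 12 raw signals, equal within 0.05, for all 25697 probes.

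The analysis planned before the data were examined was to start from the raw table with a background model and quantile normalization. That plan was not followed, because the array codes could not be tied to samples, and the authors' normalized intensities took its place. The log2 offset of 50 was chosen after the values had been seen, to keep the negative values. Fold changes are on the scale of intensity plus 50 and are therefore compressed for dim genes. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which kept 15765 probes. Each gene was represented by its kept probe with the highest mean, giving 11705 genes, of which 2935 had several kept probes. The least sensitive array detected 52.1% of its probes. A normalized intensity of 27.9, the level exceeded by that share of the values, served as an approximate floor, and changes against a group below it are given as "at least" a fold.

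Depth on an array is its number of detected probes, which lay between 13389 and 15037. The median raw intensity over the 12 array codes ran from 120.4 to 212.4. Since the codes were not tied to samples, brightness, slide and genotype could not be told apart. With 3 arrays per group, their number limits the precision.

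Differences were tested with limma 3.58.1 in R 4.3.3. One model with a mean for each of the 4 groups was fitted to all 12 arrays, with 8 residual degrees of freedom, and 6 contrasts were taken: the diet effect in each genotype, the knockout effect on each diet, the knockout effect averaged over both diets, and the difference between the diet effects. P-values were two-sided and were adjusted by Benjamini and Hochberg over the 11705 genes within a contrast, with a threshold of 0.05. Errors of log2 changes are standard errors from this fit, except where an error over genes is named. The Siah2 probe was also tested with an exact two-sided permutation over all 924 splits of the 12 arrays. For 3 arrays against 3 the smallest exact two-sided p is 0.1, so single comparisons of that size rest on limma, which borrows the spread across genes.

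Before the data were examined, 38 lists with 728 symbols were fixed, covering immune cells, adipocyte functions, metabolic pathways, stress and signalling responses, and cell types or tissues that a fat sample can hold. Each list was tested in each contrast with camera at its preset correlation of 0.01, adjusted over the 38 lists, and again with the correlation estimated from the data. With the estimate no list passed in any contrast, the lowest adjusted p being 0.0834. The test fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, was run beside it and called 25, 13, 13, 1, 10 and 1 lists in the 6 contrasts in the order above. Genes were named by a rule fixed at the same time: Siah2, Siah1a and Siah1b in every group, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (within both diets for the averaged contrast), the 10 smallest p-values for the difference between diet effects, and up to 4 called members per list, or up to 2 uncalled members given as values. A few genes that the rule picked are not reported here, and the counts include them.

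The limma step was tested on simulated data with 200 changed genes and independent normal noise. The simulation left out normalization, filter and probe choice, and held no correlation between genes, no tract content and no deviating arrays. Its rates can therefore differ from those in the real data. Of genes given a 2-fold change limma recovered between 65.7% and 80.6% in the contrasts of 3 arrays against 3, and 32.8% for the difference between diet effects. False calls numbered 5 to 13 per contrast.

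Alternatives covered the filter on dim probes, the probe chosen per gene, the variance model, array weights, the replicate number as a block, the arrays in the fit, a fold minimum and each array left out in turn. Other offsets, a floor of 16, cyclic loess, a stricter detection filter, a covariate for male reproductive tract transcripts and the omission of a pair of arrays were added after seeing the data. The covariate was the mean log2 value of 16 epididymal genes taken from the list fixed beforehand. The epididymis and testis list holds those genes, so a loss of its call with the covariate is built in and tests nothing. A list of 8 seminal vesicle genes was written after the values had been seen. Gene positions came from a reference table of mouse genes, and 582 genes tested had none. Other normalizations of the raw signals need columns tied to samples and could not be run.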

Results

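Gene expression in epididymal fat was measured in 20-week-old male C57BL/6J mice that had been fed a diet with 10% or 45% fat from 4 weeks of age. Siah2, the gene disrupted in the knockout mice, encodes a ubiquitin ligase, an enzyme that marks proteins for breakdown. The 12 arrays fell into 4 groups of 3 RNA pools: wild type on low fat, wild type on high fat, knockout on low fat and knockout on high fat. Each array detected between 13389 and 15037 probes. Correlations of log2 values between arrays of a group, across genes, which are not independent replicates, lay between 0.968 and 0.984 for wild type on low fat and between 0.982 and 0.985 for wild type on high fat. They lay between 0.943 and 0.983 for knockout on low fat and between 0.946 and 0.981 for knockout on high fat. All values below are means of 3 pools per group, n = 3, unless another n is given, and all adjusted p-values for single genes are from limma.

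The Siah2 probe was compared between genotypes to check the labels. Its intensity was 99.0 ± 15.6 (SD, n = 6) in wild type and 66.0 ± 19.3 (SD, n = 6) in knockout, with an exact permutation p of 0.0108. The log2 difference averaged over both diets was -0.37 (SE 0.11, adjusted p = 0.0795), which did not pass the threshold over all genes tested. The array labelled knockout on low fat, replicate 1, stood at 101.9, within the wild type range of 78.6 to 121, while the other knockout arrays reached at most 68.2. All 12 arrays detected the probe, and its position relative to the disrupted part of the gene is not given in the sources used here. Siah1a, a related ligase, stood at 507 ± 34.2 (SD), 451 ± 75.8, 442 ± 63.0 and 435 ± 28.8 in wild type on low fat, wild type on high fat, knockout on low fat and knockout on high fat. Siah1b stood at 87.0 ± 21.0, 96.6 ± 13.9, 77.4 ± 3.69 and 83.4 ± 8.85 in the same order. Neither passed the threshold in any of the 6 contrasts. The list of the Siah family and reported Siah2 partners had its lowest adjusted p from camera, 0.0538, for knockout on low fat diet, where Nr3c1, the glucocorticoid receptor, was higher by 1.29 (SE 0.16, adjusted p = 0.0069) and Nr1h3, an oxysterol receptor, by 0.73 (SE 0.19, adjusted p = 0.045). With the mean of epididymal genes described next as a covariate, Nr3c1 was 1.23 (SE 0.23) and Nr1h3 0.38 (SE 0.23, adjusted p = 0.613), and neither was called.

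**Figure D1:**
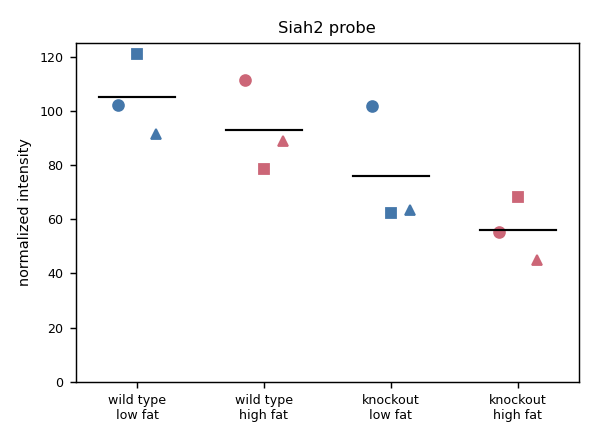
Normalized intensity of the Siah2 probe on each array (vertical axis, arbitrary units) for the 4 groups, blue for low fat and red for high fat; circles, squares and triangles are replicates 1, 2 and 3 and lines are group means. The circle of knockout on low fat stands at 101.9, and the other knockout arrays are at 68.2 or below.

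Transcripts of the male reproductive tract, which lies beside this fat depot, differed between the groups and between arrays of a group. The mean log2 value of 16 epididymal genes was 12.39 ± 1.0 (SD) in wild type on low fat, 6.63 ± 0.26 in wild type on high fat, 9.52 ± 1.17 in knockout on low fat and 7.14 ± 2.03 in knockout on high fat. The mean of 8 seminal vesicle genes was 13.99 ± 1.41, 5.73 ± 0.06, 8.99 ± 0.15 and 5.82 ± 0.19 in the same groups. Within knockout on high fat, replicate 2 stood at 9.48 for the epididymal genes and the other arrays at 5.97 and 5.95. Within knockout on low fat the arrays stood at 9.76, 8.25 and 10.55. The skeletal muscle list averaged 9.37 on the array labelled knockout on low fat, replicate 1, and 6.81 and 6.90 on the other arrays of that group. The tract means differed between diets and between genotypes on low fat diet, and each count of changed genes below is therefore also given with the epididymal mean as a covariate.

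**Figure D2:**
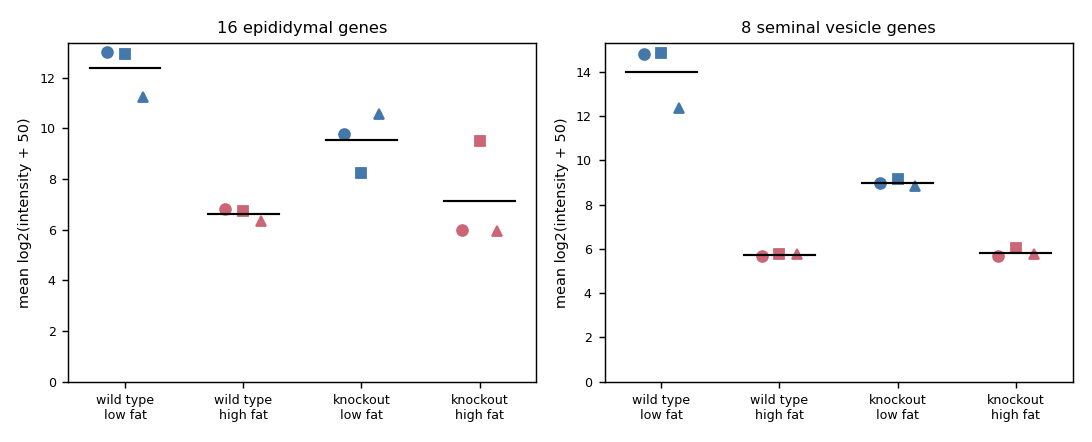
Mean log2 value (intensity plus 50) on each array of 16 epididymal genes (left) and 8 seminal vesicle genes (right), blue for low fat and red for high fat; circles, squares and triangles are replicates 1, 2 and 3 and lines are group means. Wild type on low fat has the highest group mean in both panels, 12.39 and 13.99.

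The first comparison asked how the high fat diet changed the fat of wild type mice. Mmp12, a macrophage elastase, rose from 142 ± 66.5 (SD) to 7906 ± 1058, a log2 change of 5.44 (SE 0.43, adjusted p = 2.6e-05). Trem2, a lipid receptor of macrophages, rose from 107 ± 14.2 to 3223 ± 704, by 4.37 (SE 0.26, adjusted p = 8.7e-06). Tph2, an enzyme of serotonin synthesis, rose by 5.66 (SE 0.46), Ubd, a ubiquitin-like protein, by 5.19 (SE 0.34), and Saa3, an acute phase protein, by 4.07 (SE 0.46). Rgs1, a regulator of G protein signalling, was at least 25.2-fold higher, and Slc5a7, Il7r, Slc15a3 and Cd68 rose by 4.05, 4.05, 3.86 and 3.74. The largest falls were seminal vesicle and epididymal transcripts: Svs5 was at least 398-fold lower, Svs4 353-fold, Svs1 243-fold, Gpx5 239-fold, Svs3b 229-fold, Pate4 223-fold, Svs2 173-fold and Pate14 163-fold, each as a lower bound. Spag11b changed by -8.11 (SE 0.46) and Spink1 by -7.93 (SE 1.3).

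Macrophage genes rose as a group in wild type. Of 15 measured members of the macrophage list, 14 rose and 1 did not pass (15 rose when adjusted over the list alone), with a median of 1.78 and examples Cd68, Tyrobp (3.27), Ctss (2.90) and Adgre1 (2.41). Camera gave an adjusted p of 6.19e-09, and the adjusted p was 0.33 with an estimated correlation. In the list of lipid-associated macrophages 10 of 13 members rose (11 adjusted over the list alone; camera adjusted p = 2.54e-08, and adjusted p = 0.33 with an estimated correlation), among them Gpnmb (3.4), Ctsk (2.86) and Lipa, the lysosomal acid lipase (2.45). Of 12 resident or alternatively activated macrophage genes 8 rose, as many as adjusted over the list alone, among them Mrc1 (1.37) and Mgl2 (1.44). Camera's adjusted p was 0.00501, and the adjusted p was 0.547 with an estimated correlation. Of 20 cytokine and chemokine genes 14 rose, also 14 adjusted over the list alone, among them Il1rn, an interleukin-1 antagonist (3.11), Ccl9 (2.86) and Ccl6 (2.74). Camera's adjusted p was 5.82e-05, and the adjusted p was 0.33 with an estimated correlation. Antigen presentation genes rose in 11 of 13 cases and fell in 1, with the same counts adjusted over the list alone, among them H2-DMb1 (2.38) and Ciita, the regulator of class II genes (1.97), at a camera adjusted p of 0.000105 and an adjusted p = 0.353 with an estimated correlation.

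Matrix, proliferation and fat expansion genes moved the same way. Of 26 extracellular matrix genes 23 rose, also 23 adjusted over the list alone, among them Col1a1 (1.66) and Mmp2 (1.56). Camera's adjusted p was 3.59e-09, and the adjusted p was 0.33 with an estimated correlation. Of 19 cell cycle genes 15 rose, also 15 adjusted over the list alone, among them Tk1 (1.83) and Cenpa (1.65). Camera's adjusted p was 1.01e-06, and the adjusted p was 0.33 with an estimated correlation. Of 10 adipose expansion genes 7 rose (8 adjusted over the list alone; camera adjusted p = 0.000325, and adjusted p = 0.353 with an estimated correlation), among them Fgf13 (2.39), Mest (1.91) and the hormone leptin, Lep (1.42). Lysosome genes rose in 12 of 22 cases and fell in 2 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00221, and adjusted p = 0.33 with an estimated correlation). Smaller rises were those of fatty acid oxidation (11 of 19, 12 adjusted over the list alone, camera adjusted p = 0.00929), endothelium (9 of 14, 10 adjusted over the list alone, 0.00421) and fibroblasts (11 of 16 with 2 falls, the same adjusted over the list alone, 0.0288). Their adjusted p-values were 0.443, 0.553 and 0.443 with an estimated correlation, and the fibroblast list was not called without wild type on high fat, replicate 2 (adjusted p = 0.0522). With the epididymal mean as a covariate the 3 lists were not called, with medians of 0.0097, 0.039 and 0.42 and adjusted p-values of 0.675, 0.722 and 0.129.

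The falling lists in wild type were led by the epididymis and testis list, in which 17 of 19 members fell, also 17 adjusted over the list alone, with a median of -5.50, also -5.50 with values below the floor set to it, a camera adjusted p of 3.59e-09 and an adjusted p = 0.33 with an estimated correlation. In the unfolded protein response list 10 of 20 members fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00751, and adjusted p = 0.353 with an estimated correlation). Creld2 (-1.71) and Pdia4 (-1.4), which serve protein folding in the endoplasmic reticulum, fell. The stress-induced factor Atf3 rose by 3.63. Ribosomal protein genes fell in 6 of 21 cases (3 adjusted over the list alone; camera adjusted p = 0.00225, and adjusted p = 0.443 with an estimated correlation). Skeletal muscle genes fell in 4 of 13 cases and in none adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.618 with an estimated correlation). Over the whole genome 4625 of 11705 genes changed, 2663 higher and 1962 lower. Over all genes tested the arrays of both diets did not overlap for 6034, where chance gives 10% of genes, or 1170.5. With the epididymal mean as a covariate 23 genes changed, and over the 4625 genes the median ratio of the log2 change with it to that without it was 0.532, while the median SE went from 0.17 to 0.36. The 23 included Trem2 (4.49), Gpnmb (3.66), Slc15a3 (3.60) and Lipa (2.53), while the macrophage median became 1.54, the lipid-associated macrophage median 2.07 and the matrix median 0.84, all still called by camera. The resident macrophage (median 0.56, adjusted p = 0.286), skeletal muscle (-0.88, 0.164), unfolded protein response (-0.089, 0.906), ribosomal protein (-0.042, 0.769) and epididymis and testis (0.044, 0.547) lists were not called with the covariate. For the last list this follows from the covariate, which was taken from its genes. With cyclic loess 2040 of the called genes were higher and 2608 lower.

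The same diet was then examined in knockout mice. Tph2 rose by 4.81 (SE 0.46, adjusted p = 0.0009), Ubd by 4.21 (SE 0.34) and Mmp12 from 295 ± 196 (SD) to 5205 ± 2181, by 3.97 (SE 0.43, adjusted p = 0.00203). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 3.17 (SE 0.24), Trem2 from 122 ± 54.4 to 1415 ± 418, by 3.09 (SE 0.26), Rgs1 by 3.06, Slc5a7 by 2.83, Cd68 by 2.69, and Saa3 and Slc15a3 by 2.63 each. Falls were those of Acsm3, an acyl-CoA synthetase (-2.23, SE 0.25), Cyp2f2, a cytochrome P450 (-2.16, SE 0.39), and Fam13a (-1.7, SE 0.21). Pck1, an enzyme of glyceride and glucose synthesis, fell from 3801 ± 532 to 1280 ± 283, a log2 change of -1.55 (SE 0.32, adjusted p = 0.024). Svs5 changed by -4.84 (SE 0.25). Svs4, Svs1, Svs3b, Svs2 and Spag11b were at least 27.4, 7.77, 4.55, 4.06 and 2.27-fold lower.

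In knockout mice 11 of 15 macrophage genes rose (12 adjusted over the list alone), with a median of 1.08, a camera adjusted p of 3.12e-14 and an adjusted p = 0.109 with an estimated correlation. Of 13 lipid-associated macrophage genes 10 rose (11 adjusted over the list alone), with a median of 1.38 (1.21 with values below the floor set to it), a camera adjusted p of 1.62e-15 and an adjusted p = 0.0834 with an estimated correlation. Cytokine and chemokine genes rose in 8 of 20 cases (11 adjusted over the list alone), among them Ccl2, a monocyte attractant (2.11), and Il1rn (1.96). Camera's adjusted p was 3.27e-09, and the adjusted p was 0.0834 with an estimated correlation. Antigen presentation genes rose in 6 of 13 cases (9, with 1 fall, adjusted over the list alone; camera adjusted p = 3.18e-07, and adjusted p = 0.159 with an estimated correlation). Matrix genes rose in 11 of 26 cases (22 adjusted over the list alone; camera adjusted p = 4.44e-14, and adjusted p = 0.109 with an estimated correlation), among them Timp1 (1.95). Cell cycle genes rose in 7 of 19 cases (12 adjusted over the list alone; camera adjusted p = 3.74e-12, and adjusted p = 0.109 with an estimated correlation).

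Several further lists were called by camera in knockout mice, with few members past the threshold. Of 17 fatty acid synthesis genes 3 fell (4 adjusted over the list alone), Elovl6 (-1.47), Tkt (-0.75) and Aacs (-0.59). The list had a camera adjusted p of 0.00201 and an adjusted p = 0.383 with an estimated correlation. Clock genes fell in 2 of 13 cases (7, with 1 rise, adjusted over the list alone; camera adjusted p = 4.18e-05, and adjusted p = 0.109 with an estimated correlation). They were Ciart (-0.90) and Nr1d2, a nuclear receptor of the clock (-0.59). Cholesterol synthesis genes rose in 2 of 17 cases (3 adjusted over the list alone; camera adjusted p = 0.00945, and adjusted p = 0.259 with an estimated correlation), Dhcr7 by 1.09 and Insig1 by 0.81, and this list was not called without knockout on low fat, replicate 2 (adjusted p = 0.0845). Without replicate 2 of both knockout groups the fatty acid synthesis (adjusted p = 0.0623) and cholesterol synthesis (0.189) lists were not called. In all, 513 genes changed, 417 higher and 96 lower. Over all genes tested the arrays did not overlap for 2580, where chance gives 10% of genes, or 1170.5. The count became 26 with the epididymal covariate, where the 513 genes kept their sign, with a median ratio of 0.906 to the change without it and a median SE of 0.22 in place of 0.18. It was 140 without replicate 3 of either knockout group, 177 without the array labelled knockout on low fat, replicate 1, 256 without knockout on high fat, replicate 1, and 848 without knockout on low fat, replicate 2. It was 134 when the wild type arrays were left out of the fit. Without replicate 2 of both knockout groups it was 1586, with 893 higher and 693 lower.

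Whether Siah2 alters the response to the diet was addressed by setting both responses side by side. Across the 11705 genes, which are not independent replicates, the log2 changes in knockout and wild type had a Pearson r of 0.813 and a Spearman rho of 0.686, with a slope of 0.367 in knockout against wild type. Of the called genes 409 rose in both genotypes, where independent calls would give 94.9, and 63 fell in both, where they would give 16.1. By limma 0 genes were called in opposite directions, and 26 were opposite at an unadjusted p under 0.05 in both genotypes, against 1578 in the same direction. Among genes called in both genotypes the median ratio of the knockout change to the wild type change was 0.650. The epididymal mean itself changed by -5.76 with diet in wild type and by -2.39 in knockout. Unequal tract content can therefore enter the correlations, the slope and the ratio. They do not separate it from a weaker response to the diet in knockout.

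**Figure D3:**
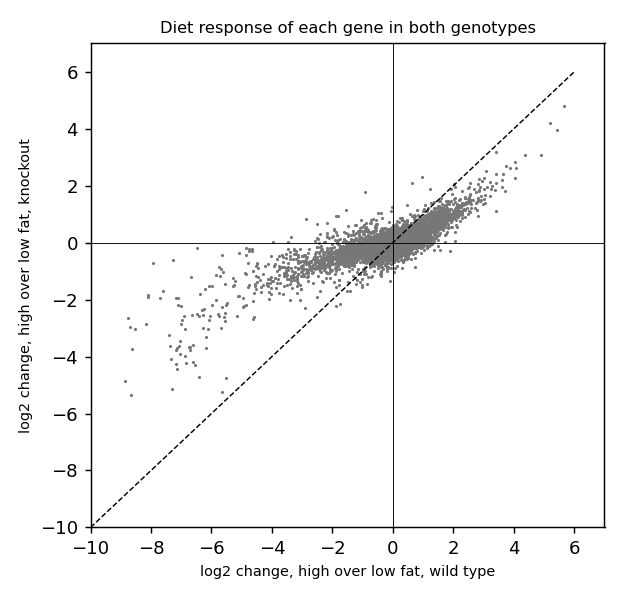
Each point is 1 of the 11705 genes, with its log2 change from low to high fat diet in wild type (horizontal axis) and in knockout (vertical axis); the dashed line marks equal changes. The points follow a slope of 0.367, with the largest falls at the left in wild type.

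The difference between the diet effects passed the threshold for 12 genes, 7 with a more positive change in knockout and 5 with a more negative one. The 7 were the tract genes Defb45 (6.28, SE 0.51), Spag11b (6.20, SE 0.65), Svs3b (5.74, SE 0.80), Svs1 (4.89, SE 0.66), Svs5 (4.02, SE 0.35) and Svs4 (3.32, SE 0.30), together with Wfdc1, a protease inhibitor (1.83, SE 0.24, adjusted p = 0.0147). Among the others were Vsig8, an immunoglobulin superfamily protein (-2.31, SE 0.25, adjusted p = 0.0052), Gdf3, a growth factor of the TGF-beta family (-1.68, SE 0.21), Kcnn4, a potassium channel (-1.22), and Treml1 (-1.11). Except for Wfdc1 and Kcnn4 these genes had at least 1 group below the floor, so their differences are fitted values and neither exact nor bounds. With values below the floor set to it they were 5.87 for Defb45, 6.69 for Spag11b, 5.65 for Svs3b, 4.97 for Svs1, 3.90 for Svs5, 3.69 for Svs4, -2.19 for Vsig8, -1.48 for Gdf3 and -0.65 for Treml1. Vsig8 rose from the background to 489 ± 71.0 (SD) in wild type and stood at 70.5 ± 33.3 in knockout on high fat. The count moved by over 1.5 times in 8 of the fits that left out 1 array. It was 5 without wild type on low fat, replicate 2, without wild type on high fat, replicate 2, or without knockout on high fat, replicate 1, 6 without wild type on high fat, replicate 1, and 7 without knockout on high fat, replicate 2. It was 44 without knockout on high fat, replicate 3, 101 without wild type on low fat, replicate 3, and 124 without the array labelled knockout on low fat, replicate 1. With the epididymal covariate, and also without replicate 2 of both knockout groups, it was 3: Defb45, Svs4 and Svs5.

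Among the lists, the macrophage list rose less in knockout, with a median difference of -0.70 and no member past the threshold by limma, 10 of 15 at an unadjusted p under 0.05 and 6 lower when adjusted over the list alone. Camera gave an adjusted p of 0.000187, and the adjusted p was 0.501 with an estimated correlation. For lipid-associated macrophages the median difference was -0.91 (-0.86 with values below the floor set to it), with no member past the threshold by limma, 9 of 13 at an unadjusted p under 0.05, and 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.501 with an estimated correlation). Examples given as values were Fabp5 (-1.55, adjusted p = 0.079) and Lipa (-1.23, adjusted p = 0.085). These medians were -0.66 and -0.79 with the epididymal covariate, and -0.47 and -0.79 without replicate 2 of both knockout groups. Both lists were still called by camera in each case.

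The knockout effect on low fat diet asked what loss of Siah2 does without the obesogenic diet. Enpep, an aminopeptidase, rose from 132 ± 34.9 (SD) to 578 ± 38.3, by 1.80 (SE 0.27, adjusted p = 0.0129), Lctl by 1.70 (SE 0.30) and Abcd2, a peroxisomal fatty acid transporter, from 1558 ± 530 to 4645 ± 478, by 1.59 (SE 0.26, adjusted p = 0.0173). Prkar2b, a regulatory subunit of protein kinase A, rose by 1.58, Kitl by 1.56, Orm2, an acute phase protein, by 1.53, Zbtb7a by 1.52, Fgf13 and Gbp5 by 1.49 each and Wasf2 by 1.41. The largest falls were again tract genes: Spag11b (-7.03, SE 0.46), Pate14 (-6.3), Svs3a (-5.87), Sva (-5.86), Spink1 (-5.66), Svs3b (-5.65), Gpx5 (-5.57), Svs6 (-5.47) and Svs2 (-5.41). Defb45 was at least 58.6-fold lower.

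Adipocyte and fuel metabolism lists were higher in knockout on low fat diet by camera, though most members of each did not pass the threshold. The epididymal mean was 12.39 in wild type and 9.52 in knockout on this diet. These values therefore do not separate a change in fat cells from a difference in tract content. Of 28 adipocyte genes 8 rose (16 adjusted over the list alone), with a median of 0.61, a camera adjusted p of 1.24e-06 and an adjusted p = 0.39 with an estimated correlation. Examples were Acsl1, an acyl-CoA synthetase (0.87), Cidec, a lipid droplet protein (0.82), and Pnpla2, a triglyceride lipase (0.79). Fatty acid oxidation genes rose in 7 of 19 cases (12 adjusted over the list alone; camera adjusted p = 6.17e-06, and adjusted p = 0.368 with an estimated correlation), among them Acadm and Hadhb (0.66 each). Fatty acid synthesis genes rose in 7 of 17 cases (8, with 1 fall, adjusted over the list alone; camera adjusted p = 0.000971, and adjusted p = 0.39 with an estimated correlation), among them the malic enzyme Me1 (1.33), Acss2 (1.13) and the transcription factor Srebf1 (0.82). Tricarboxylic acid cycle genes rose in 7 of 19 cases (9 adjusted over the list alone; camera adjusted p = 1.21e-06, and adjusted p = 0.368 with an estimated correlation), among them Pcx (0.75) and Dlat (0.64). Oxidative phosphorylation genes rose in 2 of 30 cases (5 adjusted over the list alone), with a median of 0.25, a camera adjusted p of 0.000486 and an adjusted p = 0.434 with an estimated correlation. Branched-chain amino acid breakdown genes rose in 2 of 15 cases (5 adjusted over the list alone; camera adjusted p = 0.000971, and adjusted p = 0.39 with an estimated correlation), Mccc1 by 1.16 and Hibadh by 0.49. Adipose expansion genes rose in 4 of 10 cases (6 adjusted over the list alone; camera adjusted p = 0.000486, and adjusted p = 0.368 with an estimated correlation), among them Npr3 (0.94) and Lep (0.72).

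The epididymis and testis list fell in 7 of 19 cases (11 adjusted over the list alone), with a median of -2.43 (also -2.43 with values below the floor set to it, and -3.65 without knockout on low fat, replicate 3), a camera adjusted p of 7.53e-07 and an adjusted p = 0.368 with an estimated correlation. Ribosomal protein genes fell in 4 of 21 cases (7 adjusted over the list alone; camera adjusted p = 3.78e-06, and adjusted p = 0.368 with an estimated correlation). In all, 922 genes changed between genotypes on low fat diet, 550 higher and 372 lower, while with cyclic loess 334 of the called genes were higher and 538 lower. Over all genes tested the arrays did not overlap for 3862, where chance gives 10% of genes, or 1170.5. With the epididymal covariate 4 genes were called, although all 922 kept their sign, with a median ratio of 0.777 to the change without it and a median SE of 0.21 in place of 0.16. Enpep became 1.72 (SE 0.38), Abcd2 1.38 (SE 0.37), Me1 1.33 (SE 0.28) and Pnpla2 0.48 (SE 0.18), none of them past the threshold. The count became 58 without replicate 2 of both knockout groups, and it was 4 when the high fat arrays were left out of the fit. Without 1 array it was 28 (wild type on low fat, replicate 2), 33 (knockout on low fat, replicate 2), 66 (knockout on low fat, replicate 3), 168 and 508 (wild type on low fat, replicates 1 and 3), 570 (knockout on high fat, replicate 1) and 1553 (the array labelled knockout on low fat, replicate 1). With the covariate the adipocyte median became 0.36 and that of the tricarboxylic acid cycle 0.27, both still called by camera. The epididymis and testis list, from which the covariate was taken, was not called (median -0.25, adjusted p = 0.618), which follows from that choice.

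The knockout effect on high fat diet addressed inflammation in obese fat, the subject of the study's title. By limma 10 genes were lower in knockout and 0 were higher, and 1351 had an unadjusted p under 0.05, where 585 would be expected by chance. Vsig8 fell from 489 ± 71.0 (SD) to 70.5 ± 33.3, a log2 change of -2.19 (SE 0.18, adjusted p = 0.00122). Gdf3 was at least 2.78-fold lower (SE of its log2 change 0.15, adjusted p = 0.00122). Adam8, a metalloprotease of leukocytes, fell from 269 ± 54.2 to 87.2 ± 21.2, a log2 change of -1.21 (SE 0.16, adjusted p = 0.0211). Kcnn4 (-1.2, SE 0.13), Syngr1 (-1.21, SE 0.17) and Arhgap9, a GTPase activator (-1.02, SE 0.14), fell as well. So did Hmga1, a chromatin protein (-0.83, SE 0.12), and Sh3bp2, an adaptor protein (-0.72, SE 0.11). Over all genes tested the arrays of both genotypes did not overlap for 2124, where chance gives 10% of genes, or 1170.5.

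**Figure D4:**
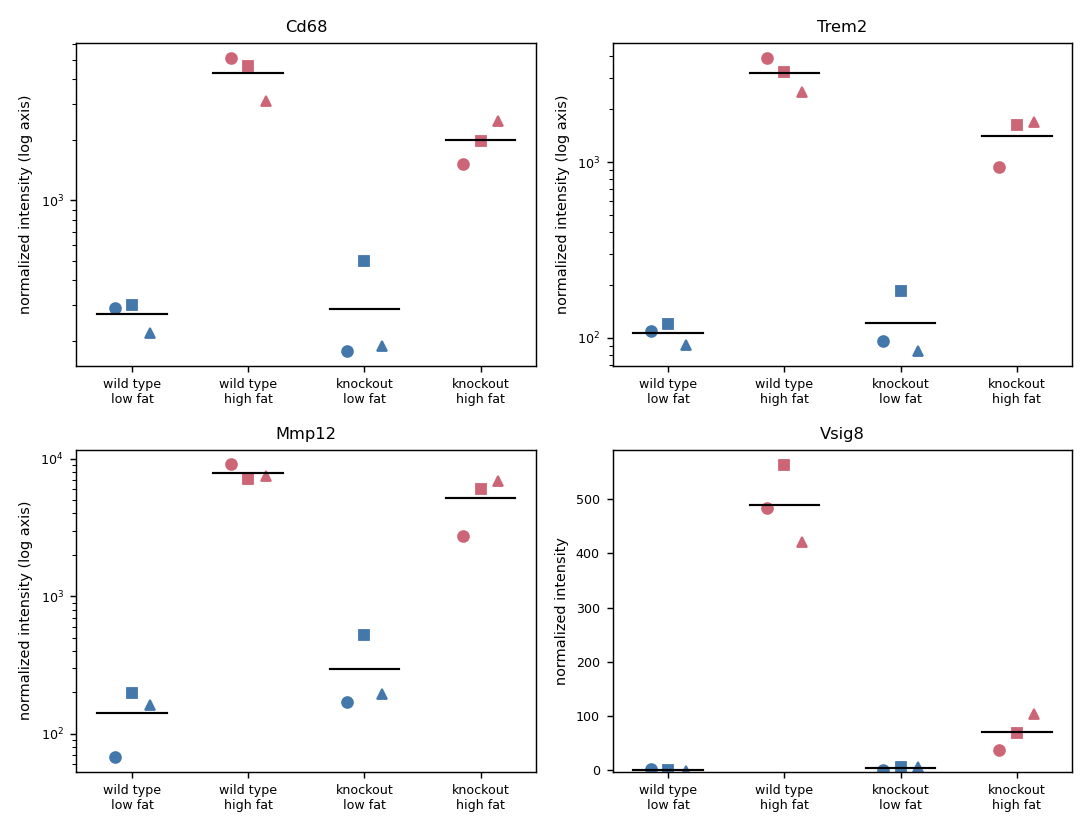
Normalized intensity on each array of Cd68, Trem2 and Mmp12 (log axes) and Vsig8 (linear axis) in the 4 groups, blue for low fat and red for high fat; circles, squares and triangles are replicates 1, 2 and 3 and lines are group means. Vsig8 averages 489 in wild type and 70.5 in knockout on high fat, while Cd68, Trem2 and Mmp12 passed the test for diet in both genotypes.

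Macrophage lists were lower in knockout on high fat diet by camera, although by limma no member passed over all genes tested. The 15 macrophage genes had a median of -0.34, with 5 at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone, a camera adjusted p of 5.04e-05 and an adjusted p = 0.718 with an estimated correlation. The 13 lipid-associated macrophage genes had a median of -0.54, with 7 at an unadjusted p under 0.05 and 7 lower when adjusted over the list alone, a camera adjusted p of 3.57e-05 and an adjusted p = 0.718 with an estimated correlation. Members given as values were Trem2 (-1.18, adjusted p = 0.15), Tyrobp (-1.07, adjusted p = 0.19) and Gpnmb (-0.96, adjusted p = 0.19). The 22 lysosome genes had a median of -0.21, with 8 at an unadjusted p under 0.05 and 6 lower when adjusted over the list alone, a camera adjusted p of 0.000908 and an adjusted p = 0.392 with an estimated correlation. It was the one list that fry called here (adjusted p = 0.00446). The 19 cell cycle genes (median -0.27, or -0.28 with values below the floor set to it, camera adjusted p = 0.000726) and the 13 antigen presentation genes (median -0.32, camera adjusted p = 0.00383) had 6 each at an unadjusted p under 0.05, with none and 4 lower when adjusted over the list alone and an adjusted p = 0.718 for both with an estimated correlation. Without wild type on high fat, replicate 1, the macrophage median was -0.19, still called by camera, and the cell cycle list was not called (adjusted p = 0.165), nor was it without knockout on high fat, replicate 1 (adjusted p = 0.0841). With the epididymal covariate 7 genes changed, and the macrophage and lipid-associated macrophage medians became -0.33 and -0.57, both still called by camera. The count was 0 when the low fat arrays were left out of the fit, and 0 with a detection p under 0.01 demanded on every array. It was 4 without replicate 2 of both knockout groups, among them Vsig8, Gdf3 and Kcnn4. Without 1 array it was 4 when that array was wild type on low fat, replicate 2, wild type on high fat, replicate 1 or 2, or knockout on high fat, replicate 1 or 2, 6 without the array labelled knockout on low fat, replicate 1, and 33 without knockout on low fat, replicate 2.

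The knockout effect averaged over both diets asked for the mean genotype effect, which a difference on a single diet can carry. Of the 324 genes called, 187 had no overlap of genotypes within both diets, as had 649 of all 11705 genes tested. Mccc1, a subunit of leucine breakdown, rose by 0.96 (SE 0.18, adjusted p = 0.0269), Mid1, itself a ubiquitin ligase, by 0.94 (SE 0.11, adjusted p = 0.00574), and Slc2a13, a myo-inositol transporter, by 0.93 (SE 0.10, adjusted p = 0.00322). L3hypdh rose by 0.91, Dld by 0.81, Ptger3, a prostaglandin E receptor, and Jam2 by 0.80 each, and Ttc33 and Map4k5 by 0.75 each. Slc2a13 stood at 402 ± 48.4 (SD) and 217 ± 21.5 in wild type on low and high fat, and at 849 ± 170 and 441 ± 12 in knockout. Lower in knockout were Entpd4 (-0.95, SE 0.13, adjusted p = 0.015), the tetraspanin Cd9 (-0.85), Gpnmb (-0.85), Fhdc1 (-0.83), Tuba6 (-0.78), Igsf9 (-0.77), Pld3 (-0.75), Ptprk (-0.74), Fam83f (-0.71) and Renbp (-0.69).

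Of 28 adipocyte genes 3 rose in the average over both diets (8, with 1 fall, adjusted over the list alone, camera adjusted p = 2.36e-06). The median of this list was 0.61 on low fat and 0.07 on high fat diet. Of 19 tricarboxylic acid cycle genes 4 rose (11 adjusted over the list alone, camera adjusted p = 2.65e-07), among them Cs, citrate synthase (0.32), and Dlat (0.42). The adjusted p was 0.358 for both with an estimated correlation. By limma 324 genes changed, 198 higher and 126 lower, while with cyclic loess 158 of the called genes were higher and 194 lower. Genes called on low fat and genes called on high fat diet had 0 in common by limma. With 10 genes called on high fat, all lower, independent calls would give 0.32 shared falls and 0 shared rises, so this overlap says little. By limma 306 genes had an unadjusted p under 0.05 on both diets with the same direction and 136 with opposite directions. Across genes, which are not independent replicates, the knockout effects on both diets had a Pearson r of -0.258 and a Spearman rho of -0.0466, and r became 0.209 with the epididymal covariate, 0.0525 without knockout on high fat, replicate 2, and 0.134 without replicate 2 of both knockout groups. Within 20 Mb of Siah2, 3 of 76 genes were called, against 304 of 11046 elsewhere (odds ratio 1.45, Fisher's exact p = 0.468), so no excess near the gene was detectable. The count of 324 became 7 with the covariate, among them Mid1, Slc2a13 and Svs5, although the 324 genes kept their sign, with a median ratio of 0.941 to the change without it and a median SE of 0.12 in place of 0.10. It was 13 without replicate 2 of both knockout groups. Without 1 array it was 143 and 27 (wild type on low fat, replicates 1 and 2), 86 and 92 (wild type on high fat, replicates 2 and 3), 157 and 29 (knockout on low fat, replicates 2 and 3), and 13, 146 and 13 (knockout on high fat, replicates 1, 2 and 3).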

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

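The tests of tract tissue, of exchanged arrays, of dilution and of wild type RNA on a knockout array were chosen after the values they measure had been seen. So was a wider error for the macrophage prediction from tract content, which left its outcome as it was. The other tests were set beforehand.

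A tested difference between the diet effects of the genotypes, knockout minus wild type, singled out 12 genes and 16 gene lists. Among the genes were the tract transcripts Defb45 (6.28), Spag11b (6.20), Svs3b (5.74), Svs1 (4.89), Svs5 (4.02) and Svs4 (3.32), with Wfdc1 (1.83), Vsig8 (-2.31), Gdf3 (-1.68), Kcnn4 (-1.22) and Treml1 (-1.11). Apart from Wfdc1 and Kcnn4 these had groups below the floor and are fitted values, which became 5.87, 6.69, 5.65, 4.97, 3.90 and 3.69 for the tract transcripts in that order and -2.19 (Vsig8), -1.48 (Gdf3) and -0.65 (Treml1) with values below the floor set to it. By limma the one list member past the threshold was Svs5, while each list held between 3 and 10 members at an unadjusted p under 0.05. Immune and matrix lists had negative medians: macrophage -0.70, lipid-associated macrophage -0.91, antigen presentation -0.56, extracellular matrix -0.57, endothelium -0.48, cell cycle -0.40 and lysosome -0.25. Their adjusted p-values from camera were 0.000187, 0.00122, 0.00306, 0.00105, 0.00778, 0.0265 and 0.0297, and each became an adjusted p between 0.501 and 0.58 with an estimated correlation. Fat cell and fuel lists also had negative medians: adipocyte -0.51, adipose expansion -0.80, fatty acid synthesis -0.40, fatty acid oxidation -0.47 and tricarboxylic acid cycle -0.28, at camera adjusted p-values of 0.00113, 0.00509, 0.0294, 0.0012 and 0.00778. With an estimated correlation these were adjusted p-values between 0.501 and 0.57. Positive medians were those of the epididymis and testis list (3.46, or 3.37 with values below the floor set to it), mesothelium (0.74), the unfolded protein response (0.22) and ribosomal proteins (0.21), at camera adjusted p-values of 2.36e-08, 0.0128, 0.00562 and 0.00131 and an adjusted p = 0.501 for each with an estimated correlation. Adjusted over the list alone, 7 epididymis and testis genes and 3 mesothelial genes were higher, while 6 macrophage, 8 lipid-associated macrophage (with 1 higher), 6 antigen presentation, 5 lysosome, 4 adipose expansion and 4 fatty acid oxidation genes were lower, and the other lists had none. With the epididymal covariate the medians of the adipocyte (-0.24), tricarboxylic acid cycle (-0.15), endothelial (-0.13), epididymis and testis (0.47), unfolded protein response (0.16) and ribosomal protein (0.10) lists were no longer called, and those of antigen presentation (-0.31), matrix (-0.32), fatty acid oxidation (-0.25) and cell cycle (-0.26) were still called. For the epididymis and testis list this follows from the covariate, which was taken from its genes. Without replicate 2 of both knockout groups the endothelial (-0.18, adjusted p = 0.106) and ribosomal protein (0.14, adjusted p = 0.0744) lists were not called. Smaller but called were macrophage (-0.47), lipid-associated macrophage (-0.79), antigen presentation (-0.32), adipocyte (-0.26), adipose expansion (-0.52), fatty acid synthesis (-0.25), tricarboxylic acid cycle (-0.18), matrix (-0.37), cell cycle (-0.25), mesothelium (0.45) and epididymis and testis (1.57). Without 1 array the fatty acid synthesis list lost its call in 4 cases (medians -0.26 to -0.46), the cell cycle list in 4 (-0.20 to -0.43), the lysosome list in 4 (-0.13 to -0.26) and the mesothelial list in 1 (0.50), the array being wild type on low fat, replicate 3, the one labelled knockout on low fat, replicate 1, and knockout on high fat, replicates 2 and 3, for the first. For the cell cycle list it was replicate 1 of any group, for the lysosome list replicate 1 of all but wild type on low fat and also knockout on high fat, replicate 3, and for the mesothelial list knockout on high fat, replicate 3. Without knockout on low fat, replicate 2, the medians of the epididymis and testis, mesothelial and adipose expansion lists were 2.12, 0.49 and -0.53, all still called, as were the endothelial list without knockout on high fat, replicate 2 (-0.32), and the lysosome list without wild type on low fat, replicate 1 (-0.13).

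The first pattern is the spread of male tract transcripts between arrays of a group, and how many of them fat itself expresses is not given in the sources used here. If tract tissue was in some fat samples, nearly all epididymal genes would be higher together on the affected array, and 0.8125 of the 16 genes were higher on knockout on high fat, replicate 2, than on both other arrays of its group. That lies between the bounds set for and against the explanation, so tract tissue in some samples may be the source but stays undecided. An exchange of knockout on low fat, replicate 2, with knockout on high fat, replicate 2, would put lipid-associated macrophage genes higher on the array labelled low fat. They were higher on the one labelled high fat by 1.35 (SE 0.334 over 13 genes, which are not independent replicates, between single arrays). The list mean was 9.64 on the first array, beside 9.10 and 9.09 in its group, and 10.99 on the other, beside 10.71 and 11.08. The seminal vesicle genes stood at 9.16 on the first array, beside 8.96 and 8.86 in its group, and at 6.04 on the other, beside 5.67 and 5.75. Both argue against an exchange, although these arrays stood at 20.3 and -9.25 on the first principal component, each on the side of the other diet, and exchanging them gave 854 called genes for the diet effect in knockout against 513, which no test here explains.

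The second pattern is the rise of macrophage genes on high fat diet in wild type, where across all 4609 called genes outside the epididymal index the changes predicted from tract content within the knockout groups correlated with those measured at 0.802 (slope 0.819, same sign in 88.8%), so that tract content stays open as a source of much of the count. These predictions draw on replicate 2 of both knockout groups, the arrays described above, and cannot tell tract content from what set that pair apart. If tract RNA had diluted the fat RNA on low fat diet, adipocyte genes would rise as much. The macrophage median exceeded the adipocyte median by 1.44 (bootstrap SE 0.299 over genes, which are not independent replicates). Over the arrays the macrophage mean went from 8.80 ± 0.24 (SD) to 10.73 ± 0.21 and the adipocyte mean from 11.30 ± 0.16 to 11.64 ± 0.10. These values argue against dilution as the whole cause. Slopes on the epididymal mean within the knockout groups predicted a macrophage median of 0.42 where 1.78 was measured, a share of 0.237. The slope of the list mean predicted 0.49, a share of 0.275, so that 1 share was just under and 1 just over the bound of 0.25. The error on the difference was 0.553, most of it from the slope, whose prediction had an error of 0.441 on 3 residual degrees of freedom. The measured median lay above both predictions. With so few degrees of freedom this leans against tract content as the whole cause without excluding it, and leaves open a part. With that mean as a covariate the list kept its call by camera, while the count of changed genes went from 4625 to 23, with a median ratio of 0.532 between the log2 changes with and without it and a median SE of 0.36 in place of 0.17, since diet and the covariate move together in wild type. A macrophage response to the diet remains a hypothesis, since an effect of diet on how the depot was dissected was not tested.

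The third pattern is the set of 922 genes that differed by genotype on low fat diet. Across the 916 of them outside the epididymal index, changes predicted from tract content within the knockout groups correlated with those measured at 0.561. The slope was 1.92, with the same sign in 83.8%. The correlation met the bound set beforehand for tract content as a source of part of the pattern. Across called genes it was 0.802 and 0.270 for diet in wild type and knockout and -0.487 for knockout on high fat (10 genes). Over all genes outside the index it was 0.545 here and 0.765, 0.628 and 0.592 in those contrasts. Over all genes it was thus not particular to this contrast. For the adipocyte list the predicted median was 0.32 here, where 0.61 was measured. For diet in wild type and in knockout it was 0.64 and 0.27, where 0.35 and -0.09 were measured. For knockout on high fat it was -0.06, where 0.07 was measured. The slopes draw on replicate 2 of both knockout groups, which deviated from their groups in opposite ways (correlation of deviations -0.812). Whatever set that pair apart enters the prediction, so the correlation cannot tell it from tract content. With the covariate 4 genes were called, among them the tract genes Defb45, Spag11b and Svs5. All 922 kept their sign at a median ratio of 0.777 while the median SE went from 0.16 to 0.21. The calls therefore ended through smaller changes and larger errors together. The covariate holds epididymal genes alone and left large falls in tract genes, not only in those of the seminal vesicle. Svs2 was -4.55 with it and -5.41 without, and Svs3b -5.14 and -5.65. Gpx5, of the epididymis and testis list, was -4.38 with it and -5.57 without, while the median of that list was -0.25 with it. The ratio therefore does not show how much of the changes tract RNA accounts for. Wild type RNA on the array labelled knockout on low fat, replicate 1, where the Siah2 probe stood at the wild type level, would place that array near wild type. Over 369 genes its median position was 0.628 from wild type (0) to the other knockout arrays (1), with 65.0% of the genes nearer to knockout. The bootstrap SE of 0.0225 is over genes, which are not independent replicates, and holds no spread between arrays. These genes were chosen for differences that tract content can also carry, and in that content the array was close to its group. Its seminal vesicle mean was 8.96, beside 9.16 and 8.86, against 13.99 in wild type on low fat. The position therefore cannot tell genotype from tract content. Wild type RNA, a mixed pool and a biological effect of genotype stay open, since no value here separates them.

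Other splits of the arrays were fitted in the same way. For the diet effect in wild type 1 of 10 splits, the real one, gave as many genes (4625, highest other 0), for the knockout effect on low fat diet 1 of 10 (922, highest other 0), and on high fat diet 1 of 10 (10, highest other 0). In knockout 2 of 10 splits gave at least as many genes for the diet effect (513, highest other 854), the other one being the split that exchanges replicate 2 of both diets, which points to a structure of the samples. A share under 0.05 cannot be reached with 10 splits. For the averaged knockout effect 1 of 100 splits, the real one, gave as many genes (324, highest other 80). Such a count was thus rare among the splits drawn, which does not exclude chance. It also rested on single arrays, being 13 without knockout on high fat, replicate 1. For the difference between the diet effects 2 of 100 splits gave as many genes as the real one (12, highest other 80). That share is under 0.05, but another split gave 80 genes against the real 12, so chance is not excluded. A split with several times the real count points to a structure of the samples.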

How the results depend on the processing

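The epididymal covariate, the omission of replicate 2 of both knockout groups, the stricter detection filter, both offsets, the floor of 16 and cyclic loess were chosen after seeing the data. The others were set beforehand. Counts of changed genes follow the order diet in wild type, diet in knockout, knockout on low fat, knockout on high fat, averaged knockout and difference between diet effects, and the values reported were 4625, 513, 922, 10, 324 and 12.

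With the epididymal covariate the counts were 23, 26, 4, 7, 7 and 3, and 9 lists instead of 16 were called for diet in wild type. The correlation of the knockout effects on both diets went from -0.258 to 0.209 and the odds ratio near Siah2 from 1.45 to 0. In wild type the diet effects of Actg2 (1.49, reported -4.59), Decr1 (-0.021, reported 1.03), Klrd1 (-0.0077, reported 0.90), Lcn8 (0.083, reported -6.25) and Ltf (1.34, reported -4.63) reversed. Lcn8 belongs to the list from which the covariate was taken, so its reversal is no separate result. Diet and the covariate move together in wild type, and the median SE of the called genes went from 0.17 to 0.36 there. Without replicate 2 of both knockout groups the last 5 counts were 1586, 58, 4, 13 and 3, 14 lists instead of 9 were called for knockout on high fat, the correlation was 0.134 and the odds ratio 0. The last 5 counts were 1099, 2552, 17, 1338 and 65 with array weights, and 301, 116, 4, 18 and 6, with an odds ratio of 0, with the replicate number as a block. Correlations of deviations between arrays with the same number ran from -0.81 to 0.16, and 1 of 12 arrays correlated best with its own number. Fitting only the groups of a contrast gave 134 (diet in knockout), 4 (knockout on low fat) and 0 (knockout on high fat), with fewer arrays to estimate the spread.

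Without the detection filter 506 genes were called for knockout on low fat and 191 for averaged knockout. An offset of 30 gave 6 genes for knockout on high fat. An offset of 100 gave 20 there, 496 for averaged knockout and an odds ratio of 0.931. Detection on every array gave 0 for knockout on high fat, 575 for averaged knockout, 1 for the difference between diet effects and an odds ratio of 0.606. A floor of 16 gave 199 for averaged knockout, and a fold minimum of 1.5 gave 109. The odds ratio was 0.861 with cyclic loess, 0.974 with a trended and robust variance and 0.780 within 50 Mb. Cyclic loess moved the median of all genes for diet in wild type from 0.06 to -0.06, and more of the called genes were then lower than higher, 2608 against 2040 there, 538 against 334 for knockout on low fat and 194 against 158 for averaged knockout. Camera called 16, 19, 13, 9, 10 and 16 lists in the order above, and 0 in each contrast with an estimated correlation. By fry 25 lists were called for diet in wild type, 1 for knockout on high fat and 1 for the difference. Except where the design or construction is named, the cause was not tested.

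Leaving out 1 array at a time gave 3530 to 4796 genes for diet in wild type, 140 to 848 for diet in knockout, 28 to 1553 for knockout on low fat, 4 to 33 for knockout on high fat, 13 to 406 for averaged knockout and 5 to 124 for the difference. The called lists ran from 11 to 20 for knockout on low fat and from 7 to 14 on high fat, the correlation from -0.377 to 0.0525 and the odds ratio from 0 to 3.07. Siah1b on low fat ran from -0.18 to 0.026 and Siah1a on high fat from -0.14 to 0.075. Of the single genes the naming rule picked, 4023 values kept direction and side of the threshold, 919 lost the call, 12 gained it and 2 reversed, and of the lists 961 kept it and 35 lost it. With the covariate 103 gene values kept it and 305 lost it, and 62 and 21 list values. Without both replicates 2 it was 300 and 111 genes, with 2 gains, and 73 and 10 lists.

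The averaged knockout count lay between 7 and 1338 over the alternatives run, and of these the covariate alone moved the count for diet in wild type by over 1.5 times. Not run, because raw columns could not be tied to samples, were the authors' separate normalized table, quantile normalization without background subtraction, a background model with median scaling, slides as a block and a detection filter within groups. Signal over background limited the dim genes: 22.9% of values were below 0, the array with the lowest share detected 52.1% of its probes, changes between 2 groups of which 1 lay below 27.9 are lower bounds, and differences between diet effects with such groups are fitted values, neither exact nor bounds.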

Other observations

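Further lists fixed before the data were examined moved with diet in knockout mice, while the spermatid mean and the principal components given last were chosen after seeing the data. Of 22 lysosome genes 4 rose (8 adjusted over the list alone; median 0.27, camera adjusted p = 8.65e-05, and adjusted p = 0.0834 with an estimated correlation). Of 10 adipose expansion genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.000766, and adjusted p = 0.286 with an estimated correlation), and of 17 immediate early and heat shock genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.118 with an estimated correlation). Of 16 fibroblast genes 2 rose (5 adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.259 with an estimated correlation). The 12 resident macrophage genes had a median of 0.66 with no member past the threshold by limma, 5 at an unadjusted p under 0.05 and 4 higher adjusted over the list alone (camera adjusted p = 0.000968, and adjusted p = 0.405 with an estimated correlation). That median was 0.44 without knockout on low fat, replicate 3, 1.11 without replicate 2 of both knockout groups, both called, and 0.37 with the epididymal covariate, where it was not (adjusted p = 0.0629). Lower by camera were branched-chain amino acid breakdown (15 genes, median -0.30, adjusted p = 0.000236), oxidative phosphorylation (30 genes, -0.14, 0.0122) and skeletal muscle (13 genes, -1.09, 0.000735), with no member past the threshold by limma or adjusted over the list alone and 5, 3 and 4 at an unadjusted p under 0.05. Their adjusted p-values were 0.286, 0.556 and 0.545 with an estimated correlation. The skeletal muscle median rested on the array labelled knockout on low fat, replicate 1, without which it was -0.36 and not called (adjusted p = 0.141), while it was -1.65 without replicate 2 of both knockout groups. The tricarboxylic acid cycle and epididymis and testis lists had 1 fall each, also 1 adjusted over the list alone, at camera adjusted p-values of 0.00759 and 2.63e-05 and adjusted p-values of 0.383 and 0.318 with an estimated correlation. Calls were also lost without knockout on high fat, replicate 2, by oxidative phosphorylation (adjusted p = 0.062), the tricarboxylic acid cycle (0.117) and the immediate early list (0.115). They were lost without knockout on low fat, replicate 2, by the tricarboxylic acid cycle (0.064) and the immediate early list (0.0527), and without knockout on high fat, replicate 3, by oxidative phosphorylation (0.080). Without replicate 2 of both knockout groups the oxidative phosphorylation (0.129), tricarboxylic acid cycle (0.350), branched-chain amino acid breakdown (0.125) and immediate early (0.229) lists were not called. With the epididymal covariate, which was taken from its genes, the epididymis and testis list was not called (0.951), while the branched-chain amino acid median became -0.46.

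Between genotypes on low fat diet, platelet and red cell genes, endothelial genes and matrix genes were higher and folding genes lower by camera. Of 7 blood genes 1 rose, the platelet chemokine Ppbp (1.41; 2 adjusted over the list alone; camera adjusted p = 0.00365, and adjusted p = 0.368 with an estimated correlation). Of 14 endothelial genes 1 rose (3 adjusted over the list alone; camera adjusted p = 0.0074, and adjusted p = 0.672 with an estimated correlation), and of 26 matrix genes 2 rose (4 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.672 with an estimated correlation). Of 20 unfolded protein response genes 2 fell, the chaperone Calr (-1.18) and Dnajc3 (-0.45; 6 adjusted over the list alone; camera adjusted p = 0.00365, and adjusted p = 0.368 with an estimated correlation). Without knockout on low fat, replicate 2, the matrix (adjusted p = 0.152) and endothelial (0.0809) lists were not called, and without wild type on low fat, replicate 1, the matrix (0.0503) and unfolded protein response (0.0526) lists were not. With the epididymal covariate the endothelial (median 0.058, adjusted p = 0.430), matrix (0.11, 0.236) and unfolded protein response (-0.020, 0.394) lists were not called, nor were the matrix (0.152) and endothelial (0.0715) lists without replicate 2 of both knockout groups. Without the array labelled knockout on low fat, replicate 1, the matrix and endothelial medians were 0.53 and 0.56. On high fat diet mesothelial genes had a median of 0.64 (0.51 with values below the floor set to it; 10 genes, camera adjusted p = 0.00405), the tricarboxylic acid cycle 0.10 (19 genes, 0.0106), oxidative phosphorylation 0.07 (30 genes, 0.0106) and matrix genes -0.19 (26 genes, 0.0386). By limma no member of these passed, 2, 3, 5 and 4 had an unadjusted p under 0.05, and the adjusted p-values were 0.718, 0.718, 0.859 and 0.976 with an estimated correlation. Without knockout on high fat, replicate 1, the tricarboxylic acid cycle (median 0.0067, adjusted p = 0.241), oxidative phosphorylation (-0.0073, 0.267) and matrix (-0.16, 0.160) lists were not called. The mesothelial median was 0.42 without wild type on high fat, replicate 2 (adjusted p = 0.0446). Without replicate 2 of both knockout groups the tricarboxylic acid cycle median was 0.20 and the matrix median -0.12, both called. The first pair also lost its call without wild type on high fat, replicate 2 (0.05014 and 0.125), and the matrix list without wild type on high fat, replicate 1 (0.458), or knockout on high fat, replicate 2 (0.0563).

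Averaged over both diets, fatty acid oxidation genes rose in 2 of 19 cases (12 adjusted over the list alone; camera adjusted p = 2.01e-05), fatty acid synthesis in 2 of 17 (7 adjusted over the list alone; 0.000819), oxidative phosphorylation in 1 of 30 (6; 2.01e-05), branched-chain amino acid breakdown in 1 of 15 (6; 0.000236), adipose expansion in 1 of 10 (1; 0.00165) and blood in 1 of 7 (1; 0.000933). Ribosomal protein genes fell in 1 of 21 cases (7 adjusted over the list alone; 2.01e-05). For each of these it was an adjusted p = 0.358 with an estimated correlation. Epididymis and testis genes fell in 2 of 19 cases (7 adjusted over the list alone, camera adjusted p = 0.00093, and adjusted p = 0.531 with an estimated correlation). This list was not called with the epididymal covariate (adjusted p = 0.983), which was taken from its genes. The lists of T and natural killer cells, B cells, neutrophils, mast cells, thermogenic fat, smooth muscle and pericytes, hypoxia, Nfe2l2 targets, the proteasome, insulin signalling and the interferon response were called by camera in none of the 6 contrasts. The sign of the median differed from the direction given by camera for 3, 2, 2, 4, 1 and 2 lists in the 6 contrasts, none of them called there.

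The mean of a pair of spermatid genes was 11.06 ± 0.41 (SD) in wild type on low fat, 9.27 ± 1.98 in wild type on high fat, 10.89 ± 1.92 in knockout on low fat and 10.89 ± 1.13 in knockout on high fat. The first principal component held 68.7% of the variance, with wild type on low fat at -58.4, -62.1 and -60.5 and wild type on high fat at 50.6, 49.5 and 50.1. Knockout on low fat stood at -39.9, 20.3 and -28.6 and knockout on high fat at 38.3, -9.25 and 49.9, for replicates 1, 2 and 3.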
